A study of Mus musculus with 29 samples.

How the data were processed

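Sequencing was of mouse OT-II CD4 T cells sorted on day 3 after immunization, per the labels' protocols, as donor cells without the recipient's CD45.1 and without B220 or MHC class II and with CD4. RNA libraries were stranded and selected for poly-A, and ATAC libraries were made with a transposase kit and read in pairs, per the labels' protocols. Libraries were grouped by the condition label into KO, control and DOX. The titles also carry a date and 1 of 4 arms, and the controls join wild-type and no-doxycycline arms. DOX recipients were given doxycycline for the first part of the response and then plain water, per the labels' protocols. Each library is a pool of cells from several recipients.

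The authors deposited raw read counts per gene and per merged ATAC peak. They also deposited CPM values per gene, log2 values per merged peak, the positions of the merged peaks, and a peak list per ATAC library with a score for each peak. BWA, Picard, MACS2, bedtools, featureCounts and edgeR are named with build mm9 per the submitters' processing notes, with no versions, settings or order, and the strand setting of the counting is not given in the sources used here. So overlapping genes, and near-identical paralogs such as Il22 and its copy, can share or lose reads. Reads in the ATAC table may or may not have been shifted to the transposase cut, which is not given in the sources used here either. The deposited CPM equal the counts per M of each library's total to within 5.1e-11, with 6785 of 23366 genes left blank, all with 0 counts. The deposited log2 values per peak differ from the log2 of the counts by an adjustment specific to each peak that takes 3 forms. One form is shared by 7 libraries, another by 5, and the last by the 2 libraries of 16 November, with a standard deviation over 15004 well-covered peaks of 0.078, 0.117 and 0.33. No source names that step. The tests below therefore use the raw counts, and the log2 table serves as an alternative. The scores are the authors' own values, all at least 5, and are used only to rank peaks within a list. Columns of other series numbered 0.

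Depth, with M for mega, was 12.3 to 15.7 M counts per RNA library in KO, 12.5 to 14.5 in controls and 8.92 to 12.6 in DOX. For ATAC it was 8.04 to 23.7 M in KO, 6.45 to 9.06 in controls and 4.79 to 21.2 in DOX. No 2 libraries of a condition agreed within sampling noise: the lowest chi-square per degree of freedom was 2.74. Each RNA library had its nearest library in its own condition (15 of 15), while 8 of 14 ATAC libraries did.

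Tests used R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter, the quasi-likelihood test with all 3 conditions in 1 fit and condition as the only term, and Benjamini-Hochberg adjustment with calls at an adjusted p under 0.05. Of 23366 genes 11316 were tested (11673 where the 4 title arms were fitted) and of 96316 merged peaks 88113. CPM in the text are scaled by TMM. The SE of a log2 fold change is approximate: its size was divided by the square root of the F value of the test. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over 29 lists, with an estimated correlation and fry as checks. The lists cover Tfh, effector, Th2, Th17, regulatory and naive T cells, T cell activation, coinhibitory and costimulatory receptors, IRF, BATF and AP-1 factors, textbook IRF4 targets, G1/S, G2/M, glycolysis, cholesterol synthesis, interferon response, apoptosis, amino acid handling, unfolded protein response and migration. Further lists hold T cell identity, sex-linked and dissociation stress genes and markers of B, plasma, myeloid, NK, CD8 T, erythroid and stromal cells.

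The text names a selection of the genes of a rule fixed before the data were examined. The rule takes 15 core genes whatever their result. It adds the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups. From each list it adds up to 4 members of smallest p. All 15 core genes are given, and of the other parts a selection. For ATAC it takes 5 peaks per direction, with at least 5 CPM. The comparisons, tests and lists were also fixed before the data were examined. Genes outside the rule are named only in the closing part, as chosen after their values were seen.

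On simulated data 200 features were changed, all of a mean level above the median, so recovery at lower levels was not measured. The RNA test recovered 99% of 2-fold changes for KO and 98% for DOX over 11316 genes, with 2.93% and 3.88% false calls. For ATAC it recovered 29% of 2-fold and 80% of 4-fold changes for KO and 23% and 74% for DOX over 88113 peaks, with 4.39% and 3% false calls. DESeq2 1.42.0 gave 45.1% and 50.9% false calls on the simulated ATAC data, which limits what its larger ATAC counts show. Camera called 0 of 20 unchanged simulated lists in either comparison, but the simulated genes were drawn independently, so this does not cover lists of genes that vary together.

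Title dates occur across conditions. They were read as shared days and taken as a pairing, though the sources used here do not say what they mark. Libraries of the same date deviated together from their condition means with a median correlation of 0.342 in ATAC (0.223 to 0.868 over 7 pairs) and 0.188 in RNA (−0.0379 to 0.25 over 8 pairs, 7 of them over 0.1). Libraries of different dates had medians of −0.0284 in ATAC (−0.556 to 0.603, 15 of 54 pairs over 0.1) and −0.0183 in RNA (−0.298 to 0.285, 13 of 66). Single pairs of different dates thus deviated together as well. In ATAC, KO replicate 1 correlated at 0.603 with control replicate 5 of its date and also with control replicate 7 of another. These libraries share a form of the adjustment given above, so its library sets and the dates are not fully told apart. The date block is an alternative to the unblocked fit. Other alternatives were DESeq2 size factors, total counts, no filter, the DESeq2 test, only the groups compared, controls of the matching title arm, cyclic loess scaling, a 2-fold limit and leaving out each library in turn. Chosen after the data were seen were the sex of the library, read from Xist and Y-linked signal, as a covariate, the log2 table, the 3 adjustment sets as a covariate, leaving out both libraries of 16 November, the date block for the relation of both ATAC effects, and swaps of condition within dates for the peak lists.

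Peak lists were compared with bedtools 2.31.1 by which merged peaks each touched (at least 1 bp). Alternatives asked for 50 percent of the merged peak or took the 10000 peaks of highest score. Groupings of the libraries, the real one included, numbered 100 per RNA comparison and up to 60 per ATAC comparison, a number lowered for run time before any ATAC count was seen. The genome and annotation of build mm9 were not used here, so nearest genes and motifs of the peaks were not analysed here.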

Results

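RNA-seq and ATAC-seq, which reads open chromatin by transposase insertion, were measured in mouse OT-II CD4 T cells, whose transgenic receptor recognises an ovalbumin peptide. The cells were transferred into congenic mice, which were immunized the next day with an ovalbumin preparation in complete Freund's adjuvant, and donor T cells were sorted on day 3. The study asked how the transcription factor IRF4 directs T helper cell fate. It compared cells from Irf4-deficient donors (KO), control cells with intact Irf4, and cells with intact Irf4 plus an inducible Irf4 construct whose recipients drank doxycycline (DOX). RNA-seq covered 15 libraries (5 KO, 6 control, 4 DOX) with 8.92 to 15.7 M counted reads each, and ATAC-seq covered 14 libraries (4 KO, 7 control, 3 DOX) with 4.79 to 23.7 M. The controls joined libraries titled wild type with inducible libraries titled as given no doxycycline. Each library pooled the cells of several mice, so the p-values measure the spread between pools. Where donors carried the inducible construct, cells were enriched by antibody depletion before transfer, a step that goes with those arms, and no arm given doxycycline without the construct was analysed here.

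Irf4 itself was counted in every library. Its level was 265 ± 51.3 CPM (counts per M reads counted, with M for mega; SD, n = 5) in the KO-labelled libraries, 318 ± 82.9 in the controls (n = 6) and 227 ± 6.67 in the DOX-labelled libraries (n = 4). The log2 fold change against the controls was −0.27 ± 0.16 (SE) in KO (adjusted p = 0.252, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and −0.49 ± 0.17 in DOX (adjusted p = 0.0548). The adjusted p in DOX ranged from 0.00784 without control replicate 2 to 0.151 against the no-doxycycline controls alone. The Irf4 count thus goes against the KO and DOX labels as a plain measure of less and more transcript. Libraries are named by label throughout, and every direction below rests on those labels. A count over the whole gene does not show whether part of it is deleted or whether protein is made.

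**Figure D1:**
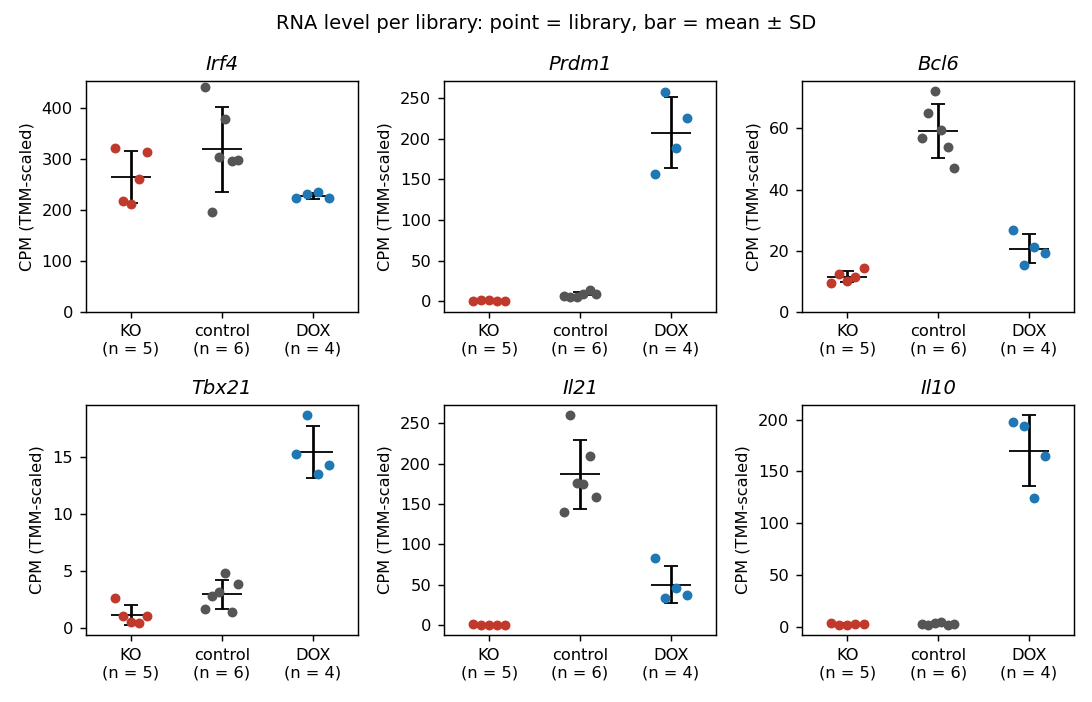
CPM per RNA library of genes fixed beforehand, with points for single libraries and bars for the mean of 5 KO-labelled, 6 control and 4 DOX-labelled libraries. Irf4 lies between 196 and 440 CPM in all 15 libraries, while Prdm1 averages 0.876, 8.25 and 207 CPM in the 3 conditions.

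The first comparison asked what changes without IRF4. In the KO-labelled libraries Il21, the cytokine of follicular helper (Tfh) cells, was 0.612 ± 0.283 CPM (SD, n = 5) against 187 ± 42.9 in controls (n = 6), a log2 fold change of −8.26 ± 0.34 (SE; adjusted p = 5.04e-11, edgeR with Benjamini-Hochberg adjustment). The Tfh receptor Cxcr5 fell from 246 ± 48.7 to 10.4 ± 2.36 CPM, and both Bcl6, the Tfh-directing repressor, and Prdm1, which encodes the opposing repressor Blimp-1, fell (log2 fold changes −2.36 ± 0.15 and −3.26 ± 0.44). Iltifb, a near-identical copy of Il22 that may share its reads, averaged 13.8 ± 10.6 CPM in controls against a sum of 1 count over the 5 KO libraries. The Th17 genes Il22 (log2 fold change −8.18 ± 1.08), Il23r (−7.67 ± 0.96) and Il17a (−7.27 ± 1.16) fell. So did the transcription factor genes Tox2 (−7.47), Cebpa (−7.41) and Rorc (−5.38 ± 0.79, the Th17-directing factor). Control levels spread widely, from 4.97 to 108 CPM for Il22, 1.31 to 33.7 for Il23r and 0.276 to 31.1 for Il17a. Rorc was at 4.15 and 1.45 CPM in the wild-type-titled controls and at 13.1 to 21.3 in the no-doxycycline ones. The size of its fall thus depends on the controls taken. Foxp3, the factor of regulatory T cells, rose from 0.9 ± 1.28 to 13.2 ± 7.56 CPM (log2 fold change 3.90 ± 0.56, adjusted p = 4.38e-05), and Mamdc2 (7.25), Rhod (6.47), Chst3 (5.65) and Pde2a (5.03) had the highest changes among the genes named here.

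Of 11316 genes tested, 2893 differed between KO-labelled and control libraries, 1480 higher and 1413 lower, and 1023 of them by 2-fold or more. With the title date as a block 1593 genes differed, and against the wild-type-titled controls alone 1406. The block rests on 3 of the 5 KO libraries, since the dates of KO replicates 1 and 4 occur in no other RNA library, and the wild-type-titled controls are 2 libraries. Tcf7, a factor of naive and Tfh cells (log2 fold change 0.09), Gata3 (0.19), Il10 (−0.24) and Batf (0.11), which encodes a partner of IRF4, did not pass, although Batf passed with the date block (0.39, adjusted p = 0.0276). Ctla4 fell (−2.05 ± 0.23), Ikzf2 (1.00 ± 0.23) rose, and Tbx21 (−1.42 ± 0.40), which directs Th1 cells, fell. Against the wild-type-titled controls alone Ikzf2 and Tbx21 no longer passed (adjusted p = 0.273 and 0.227). The interleukin-2 receptor chain gene Il2ra was higher (1.23 ± 0.41, adjusted p = 0.0356), a call that was lost without KO replicate 1 or 5 or control replicate 1, 2, 3 or 5 (adjusted p from 0.0617 to 0.113), with only both groups in the fit (0.0546) and with the sex covariate (0.054).

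The gene groups were described by lists fixed beforehand and tested with camera, which called 14 of the 29 in KO and 10 in DOX, while other groupings of the same libraries gave a median of 8 and 7. All 12 measured Th17 genes were lower in KO, and all 12 also when adjusted over the list alone (adjusted p = 6.99e-11, and 0.225 as adjusted p with an estimated correlation). They include Il17f (−6.70) and the interleukin-1 receptor gene Il1r1 (−5.50). Of 24 Tfh-associated genes 11 fell and 5 rose, or 11 and 6 adjusted over the list alone (adjusted p = 7.15e-05, and adjusted p = 0.286 with an estimated correlation), with Maf (−4.91) among those lower. Textbook IRF4 targets held their call: 15 of 22 fell and 2 rose, or 17 and 2 adjusted over the list alone, with adjusted p = 7.32e-10 and adjusted p = 0.026 with an estimated correlation. That list shares genes with others, such as Il21, Maf and Bcl6 (Tfh), Il17a and Rorc (Th17) and Prdm1 and Cxcr3 (effector). Its call is therefore not separate from theirs. Of 20 coinhibitory and costimulatory receptor genes 8 fell, such as Tigit (−5.17) and Icos (−2.15), and 6 rose, or 9 and 6 adjusted over the list alone. That list had adjusted p = 0.0186, adjusted p = 0.475 with an estimated correlation and 0.0583 without control replicate 1. Of 24 migration genes 13 fell and 4 rose, or 13 and 5 adjusted over the list alone (adjusted p = 0.000246, and adjusted p = 0.286 with an estimated correlation).

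Effector genes moved both ways in KO. Of 27 Blimp-1- or Th1-type effector genes 13 fell and 6 rose, or 14 and 6 adjusted over the list alone. The integrin gene Itgb1 (−2.53) and the chemokine receptor genes Cxcr3 (−5.18) and, from the Th2 list, Ccr4 (−3.37) fell, while the cytotoxic granule gene Nkg7 (2.88) rose. The effector list had adjusted p = 0.0493 and adjusted p = 0.483 with an estimated correlation, and it lost its call with the date block (0.0704), against the wild-type-titled controls alone (0.0592), with no filter (0.138) and without KO replicate 4 or 5 or control replicate 1, 2, 4 or 6 (0.0514 to 0.0922). Of 28 genes of naive T cells 14 rose and 2 fell, also adjusted over the list alone. Sell, which encodes the lymph node homing receptor L-selectin, rose by 1.60 ± 0.16 (SE) on the log2 scale and Foxp1 by 1.41. That list had adjusted p = 1.38e-05, and adjusted p = 0.286 with an estimated correlation. Interferon-response genes rose: 21 of 37 were higher and 2 lower, or 24 and 2 adjusted over the list alone, such as the RNA sensor gene Ddx58 (2.06) and Cmpk2 (1.84), with adjusted p = 1.34e-06 and adjusted p = 0.486 with an estimated correlation.

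Several metabolic and secretory lists had calls toward lower levels in KO. Of 23 glycolysis genes 12 fell and 1 rose, or 14 and 1 adjusted over the list alone (adjusted p = 5.88e-06, and adjusted p = 0.286 with an estimated correlation), among them Hif1a (−1.98) and the phosphofructokinase gene Pfkp (−1.06). Of 24 genes of the unfolded protein response 18 fell and none rose, on both adjustments (adjusted p = 9.48e-09, and adjusted p = 0.241 with an estimated correlation), among them Atf6 (−1.91), Manf (−0.93) and the chaperone gene Hspa5 (−0.61). Of 26 cholesterol synthesis genes 7 fell, on both adjustments (adjusted p = 0.00018, and adjusted p = 0.475 with an estimated correlation). Of 26 genes of the integrated stress response and amino acid handling 10 fell and 2 rose, or 11 and 2 adjusted over the list alone (adjusted p = 0.00801, and adjusted p = 0.503 with an estimated correlation). Of 35 G2/M genes 9 fell, such as Cdca8 (−0.37), on both adjustments, with adjusted p = 0.000672 and adjusted p = 0.601 with an estimated correlation. Against the wild-type-titled controls alone the direction of the G2/M list turned (adjusted p = 0.77), its call was lost with fry (0.0932), and Cdca8 lost its call there (0.249) and with the date block (0.0659).

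The other lists, apart from the myeloid markers given below, had no camera call in KO, and adjusted over the list alone none of their counts moved by more than 2 genes. The Th2 list had 2 genes higher and 3 lower of 9 (adjusted p = 0.256), the regulatory T cell list 7 and 3 of 12 (0.376), T cell activation 9 and 8 of 29 (0.67), IRF, BATF and AP-1 factors 7 and 5 of 32 (0.673), apoptosis 6 and 7 of 27 (0.731) and G1/S 1 and 2 of 35 (0.256, and 0.0428 without KO replicate 1). Bcl2l11, which encodes the death-promoting protein Bim, rose by 1.91 on the log2 scale. T cell identity genes split, with 2 higher such as Cd5 (1.16) and 4 lower such as Lat (−0.51) of 17 (0.67), and dissociation stress genes had 1 higher and 3 lower of 17 (0.556). For the IRF and AP-1 factor, apoptosis, T cell identity, stromal and dissociation stress lists the median, the mean and the test differed in sign. Among markers of other cells, 3 of 11 myeloid genes rose, also adjusted over the list alone, Itgam from 4.45 ± 0.948 to 10.9 ± 2.56 CPM and Fcgr3 from 0.257 ± 0.125 to 2.73 ± 0.523. The myeloid call (adjusted p = 0.0419) was lost with an estimated correlation (adjusted p = 0.483), against the wild-type-titled controls alone (0.441) and without KO replicate 2 or 3 or control replicate 2, 4, 5 or 6 (0.0513 to 0.133). B cell markers had 1 gene higher and 2 lower of 5 (0.399), plasma cell 0 and 2 of 4 (0.243), NK cell 2 and 0 of 4 (0.164, and 0.0283 with the date block), CD8 T cell 0 and 1 of 2 (0.195), erythroid and platelet 0 of 2 (0.58) and stromal 3 and 2 of 5 (0.673). None of the 5 sex-linked genes passed (0.431, and 0.0277 with the date block), with a median log2 fold change of −2.05. By Xist against the Y-linked Ddx3y, 4 KO, 2 control and 2 DOX RNA libraries were read as female and 1, 4 and 2 as male.

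**Figure D2:**
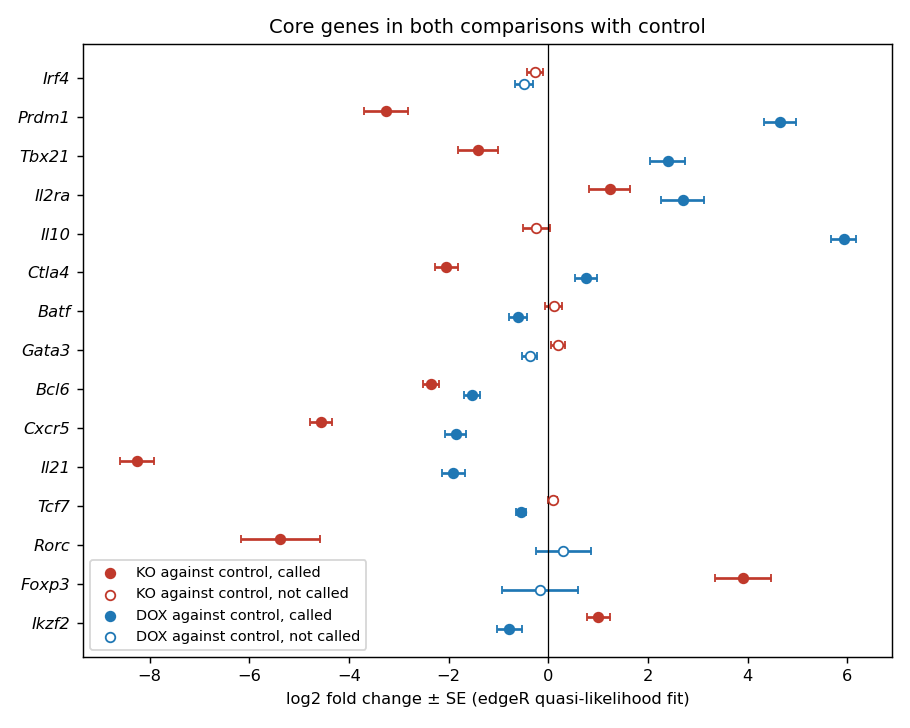
Log2 fold changes with standard errors of the genes fixed beforehand, for KO-labelled and DOX-labelled libraries against the same controls. Prdm1 lies at −3.26 in KO and 4.65 in DOX, and Bcl6 at −2.36 and −1.53.

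The second comparison asked what added IRF4 does. In the DOX-labelled libraries Prdm1 rose from 8.25 ± 3.57 CPM in controls (SD, n = 6) to 207 ± 44 (n = 4), a log2 fold change of 4.65 ± 0.33 (SE; adjusted p = 2.04e-08, edgeR with Benjamini-Hochberg adjustment). Il10, a suppressive cytokine gene, rose from 2.79 ± 1.17 to 170 ± 34 CPM (5.92 ± 0.24), Il2ra from 47.4 ± 30.3 to 306 ± 70.2 (2.69 ± 0.44) and Tbx21 from 2.93 ± 1.29 to 15.4 ± 2.30 (2.39 ± 0.35). The Tfh genes Bcl6 (−1.53 ± 0.16), Cxcr5 (−1.86 ± 0.21), Il21 (−1.90 ± 0.24) and Tcf7 (−0.55 ± 0.10) fell. The chemokine receptor genes Ccr9 (7.72) and Ccr5 (5.78) rose, while Lif (−3.62), Klrb1c (−2.99), Tnfsf8 (−2.94) and Kit (−2.81) were among the genes with the lowest changes. Klk1 averaged 29.3 ± 11.8 CPM and Spon1 27.9 ± 17.9 in DOX, against a sum of 1 and 3 counts over the 6 controls.

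In DOX 2345 of 11316 genes differed from the controls, 1332 higher and 1013 lower, and 846 by 2-fold or more. Gata3 (−0.37), Rorc (0.30) and Foxp3 (−0.17) did not pass, and with the date block the signs of Rorc (−0.34) and Foxp3 (0.73) turned without passing. Ctla4 was higher (0.75 ± 0.23, adjusted p = 0.0249), and this call was lost without DOX replicate 1 or 3 or control replicate 6 (adjusted p from 0.0512 to 0.0816). Batf was lower (−0.61 ± 0.19, adjusted p = 0.0254), a call lost without DOX replicate 2, 3 or 4 or control replicate 2 or 5 (0.0562 to 0.0882) and with only both groups in the fit (0.0595). Ikzf2 was lower (−0.78 ± 0.25, adjusted p = 0.0341), a call lost with the date block (0.0529), against the no-doxycycline controls alone (0.149), with only both groups in the fit (0.0627) and without DOX replicate 2 or 4 or control replicate 1 or 3 (0.0656 to 0.104).

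Most effector genes rose in DOX, while 9 of the 27 measured were not called. Of 27 effector genes 17 rose and 1 fell, or 18 and 3 adjusted over the list alone, and this list held its call (adjusted p = 6.2e-10, and adjusted p = 0.0474 with an estimated correlation). Ly6c2 rose by 5.51 on the log2 scale, Selplg, which encodes the selectin ligand PSGL-1, by 1.23 and the inhibitory receptor gene Havcr2 by 2.98. Tfh-associated genes fell, 15 of 24 lower and 3 higher on both adjustments (adjusted p = 1.48e-06, and adjusted p = 0.177 with an estimated correlation). Migration genes had 10 of 24 higher and 2 lower, or 11 and 3 adjusted over the list alone (adjusted p = 0.000945, and adjusted p = 0.341 with an estimated correlation), such as the integrin gene Itga4 (1.96). Naive T cell genes were higher in 9 and lower in 4 of 28, or 11 and 4 adjusted over the list alone, with Klf2 (1.86) and Foxp1 (1.55) higher. The naive call (adjusted p = 0.0419) was lost with an estimated correlation (adjusted p = 0.641), with fry (0.0511) and without DOX replicate 1, 3 or 4 or control replicate 2, 4 or 5 (0.0561 to 0.147).

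Glycolysis genes were mostly lower in DOX, 14 of 23 lower and 1 higher, or 15 and 1 adjusted over the list alone. The list had adjusted p = 2.63e-05, and adjusted p = 0.271 with an estimated correlation. The lactate exporter gene Slc16a3 (−1.81) and Gpi1 (−0.44) were among those lower. The list was also lower in KO, but both comparisons share the controls, and as a list DOX was not tested against KO. Set directly against KO, Hif1a (1.11) and Pfkp (0.59) were higher in DOX (adjusted p = 2e-04 and 3.77e-05, edgeR). Slc16a3 (−0.33) and Gpi1 (−0.09) did not differ detectably there. Hif1a and Pfkp were named for their small p in KO, and Slc16a3 and Gpi1 for theirs in DOX. The direct comparison shares those libraries, so it is no separate support. G1/S genes had 4 of 35 lower, such as Tyms (−0.43), on both adjustments (adjusted p = 0.0095, adjusted p = 0.641 with an estimated correlation and 0.098 with fry). Cholesterol synthesis genes had 5 of 26 lower and 1 higher, or 7 and 1 adjusted over the list alone. The cholesterol call (adjusted p = 0.0419) was lost with an estimated correlation (adjusted p = 0.641), with fry (0.174), with the date block (0.0724), against the no-doxycycline controls alone (0.143) and without DOX replicate 1, 3 or 4 or control replicate 3, 4 or 6 (0.0503 to 0.346).

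Th17 genes had 5 of 12 lower and 0 higher in DOX, among them Il17f (−3.72) and Il1r1 (−2.16). The list did not pass (adjusted p = 0.061) but did with the date block (0.00928), against the no-doxycycline controls alone (0.00204) and without DOX replicate 1 or 3 or control replicate 3 (0.00162 to 0.0461). Lists that moved both ways without a camera call were coinhibitory and costimulatory receptors, with 6 higher and 6 lower of 20 (adjusted p = 0.662), textbook IRF4 targets 7 and 5 of 22 (0.373) and IRF, BATF and AP-1 factors 6 and 7 of 32 (0.881). Entpd1 (4.53), Lag3 (2.22) and Ikzf3 (2.23) rose among these. Of the unfolded protein response genes 7 of 24 rose, such as Xbp1 (1.04), and 0 fell (0.108), and T cell activation genes had 1 higher and 5 lower of 29 (0.112), Cd83 (−2.40) being the lower gene of smallest p. Interferon-response genes had 3 higher and 1 lower of 37 (0.155), and passed with the date block (0.0264), against the no-doxycycline controls alone (0.00336) and without DOX replicate 2 (0.00104) or control replicate 3 (0.00932). Regulatory T cell genes had 4 higher and 1 lower of 12 (0.103), and passed with the date block (0.0146), against the no-doxycycline controls alone (0.0247) and without control replicate 1 (0.0273). Th2 genes had 1 higher and 1 lower of 9 (0.258), G2/M 1 and 0 of 35 (0.663), apoptosis 4 and 5 of 27 (0.988), integrated stress response and amino acid handling 2 and 1 of 26 (0.811), dissociation stress 0 and 1 of 17 (0.631) and sex-linked genes 0 of 5 (0.694). For the lists without a camera call no count moved by more than 2 genes when adjusted over the list alone. The median, mean and test differed in sign for the IRF4 target, apoptosis and amino acid handling lists.

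Some markers of other cell types were higher in the same DOX-labelled libraries as the effector genes above, while the NK cell marker Klrb1c (−2.99) and Acta2 (−2.46), 1 of the 3 stromal markers that changed, were lower. Itgam, an integrin gene used as a myeloid marker, rose from 4.45 ± 0.948 to 150 ± 30.1 CPM (log2 fold change 5.08 ± 0.19, adjusted p = 7.66e-12, edgeR with Benjamini-Hochberg adjustment). The CD8 coreceptor gene Cd8a rose to 18.7 ± 6.00 CPM from 0.0746 ± 0.0674 and Cd8b1 to 94.1 ± 21.4 from 8.75 ± 1.98. The stromal markers Col1a1, a collagen gene (4.56, from 0.599 ± 0.497 to 14.5 ± 5.61 CPM), and Pdgfrb (4.28, from 0.0886 ± 0.111 to 1.87 ± 0.84), the cytotoxic genes Prf1 (3.75) and Gzma (3.32) from the NK cell list, and the plasma cell markers Eaf2 (4.59) and Fkbp11 (3.28) rose as well. By list, both CD8 T cell markers rose (adjusted p = 3.45e-05, and adjusted p = 0.057 with an estimated correlation), and 2 of 4 plasma cell markers (0.00439, and adjusted p = 0.177 with an estimated correlation), on both adjustments. T cell identity genes had 6 higher, such as Cd6 (0.91), and 1 lower of 17, or 8 and 1 adjusted over the list alone (adjusted p = 0.0166), a call lost with an estimated correlation (adjusted p = 0.641) and without DOX replicate 1 (0.147). Myeloid markers had 3 higher of 11 (0.103) and passed with the date block (0.0176), against the no-doxycycline controls alone (0.0175) and without control replicate 1 (0.0407). The B cell list had 2 higher of 5 (0.112, 0.0498 against the no-doxycycline controls alone and 0.0361 without control replicate 1), NK cell 2 higher and 1 lower of 4 (0.694), erythroid and platelet 0 of 2 (0.501) and stromal 2 higher and 1 lower of 5 (0.213).

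**Figure D3:**
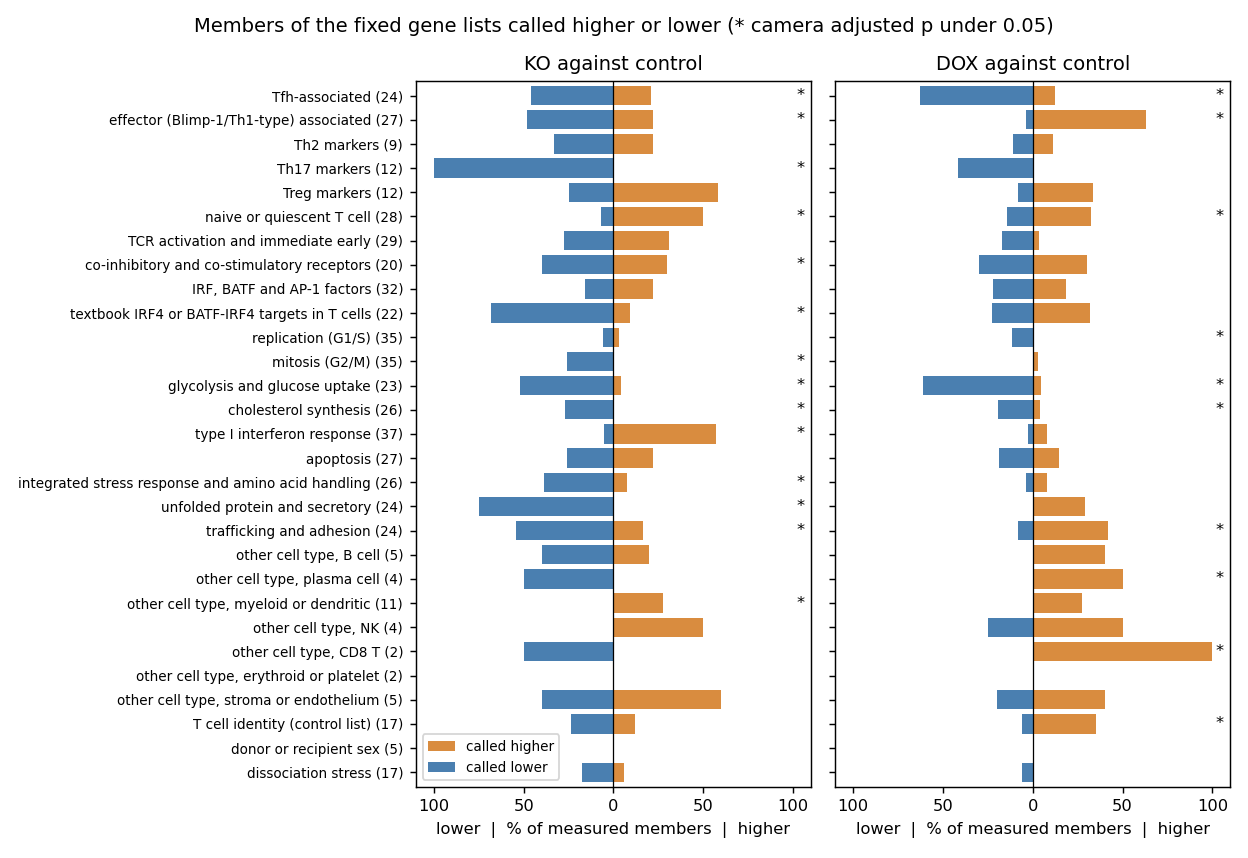
Measured members called higher or lower in each gene list fixed beforehand, for KO-labelled and DOX-labelled RNA libraries against controls. All 12 Th17 genes are lower in KO, and 17 of 27 effector genes are higher in DOX.

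Set directly against each other, DOX-labelled and KO-labelled libraries differed at 3400 of 11316 genes, 1802 higher and 1598 lower in DOX, and at 1927 with the date block, where 1 date holds both conditions. Prdm1 was higher in DOX by 7.90 on the log2 scale, Il21 by 6.36, Il10 by 6.16, Cxcr5 by 2.70 and Bcl6 by 0.83 (adjusted p = 0.000774, edgeR with Benjamini-Hochberg adjustment). Foxp3 (−4.07) and Ikzf2 (−1.79) were lower. Irf4 did not differ detectably (−0.22, adjusted p = 0.377).

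The KO and DOX effects were then set side by side across genes. Of 1035 genes called in both, 364 were higher in both, 342 lower in both, 191 lower in KO and higher in DOX, and 138 higher in KO and lower in DOX. Independent lists of those sizes would share 174.2, 126.5, 166.3 and 132.5 genes. Without DOX replicate 1 the excess among genes lower in KO and higher in DOX turned (255 against 261.5), as did that among genes higher in KO and lower in DOX (168 against 208.3), and the latter also turned with total counts (146 against 148.4) and without control replicate 1 (fewer than the 135.8 of independent lists). Bcl6, Cxcr5 and Il21 are among the genes lower in both, and Prdm1, Tbx21 and Ctla4 among those that moved apart. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.128 (Spearman 0.19) with a covariance of 0.0785, while 20 simulated sets of unchanged groups against the same controls gave a mean r of 0.411 and a covariance of 0.0235. The simulated sets hold no date pairing, and the date block was not run for this relation in RNA. With the wild-type-titled controls for KO and the no-doxycycline controls for DOX, r was 0.117 and the covariance 0.0822.

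**Figure D4:**
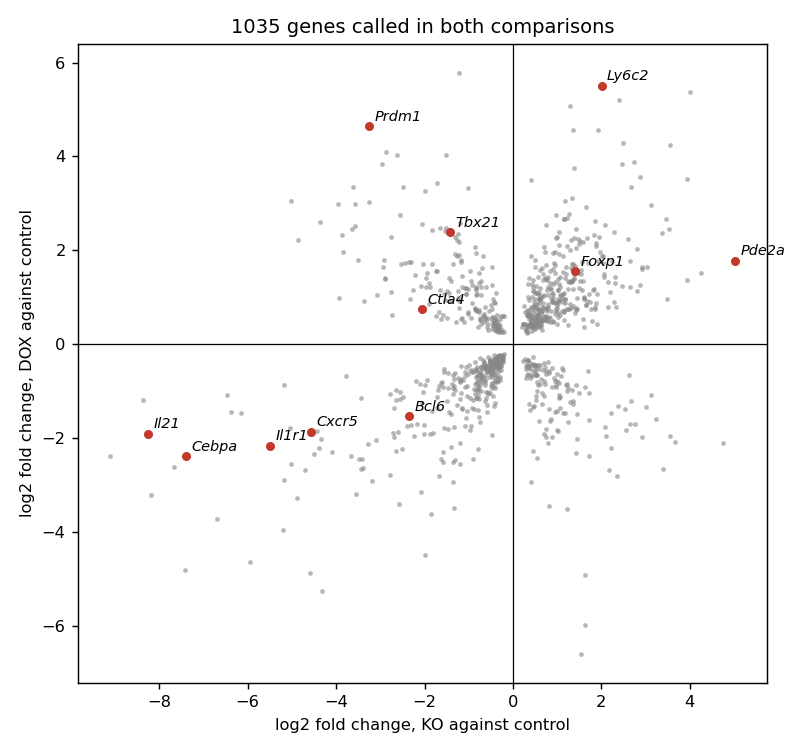
Log2 fold changes against the controls in KO-labelled and DOX-labelled RNA libraries, with the genes called in both. Of those 1035 genes, 68.2% moved the same way.

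In ATAC-seq the question was which open regions change. Regions are peaks merged by the authors over all libraries, on build mm9, with 1-based positions. No mm9 annotation was used here, so no gene is assigned. In the KO-labelled libraries (n = 4) the peak at chromosome 18, 57573584 to 57574625, had 27.8 ± 6.75 CPM against 1.91 ± 1.31 in controls (n = 7), a log2 fold change of 3.83 ± 0.41 (SE; adjusted p = 0.000256, edgeR with Benjamini-Hochberg adjustment). Peaks at chromosome 2, 173472410 to 173473172 (3.06), chromosome 13, 65010635 to 65011539 (2.98), chromosome 6, 97819209 to 97820303 (2.83), and chromosome 4, 102654120 to 102655731 (2.74), were also higher. The peak at chromosome 5, 11256096 to 11256918, fell from 25.5 ± 16.1 to 1.42 ± 0.705 CPM (−4.14 ± 0.50), and peaks at chromosome 1, 51877141 to 51878406 (−3.69) and 153899987 to 153900980 (−3.68), chromosome 8, 118263608 to 118264125 (−3.66), and chromosome 9, 7509591 to 7510528 (−3.65), fell as well. All 10 of these peaks also differed in the direct comparison, the 5 raised in KO being lower in DOX than in KO and the other 5 higher. The peaks were picked by the KO libraries that this comparison shares, so it is no separate support.

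Of 88113 peaks tested, 6952 differed in KO, 3533 higher and 3419 lower (50.8% higher), and 4931 by 2-fold or more. With total counts as the scaling 63.9% of the called peaks were higher, and the median of all peaks moved from −0.15 to −0.00495. With the date block 11379 peaks differed, 41.8% of them higher, and without KO replicate 3 there were 4248 (41.6% higher). The control library of 16 November (control replicate 2) stood apart, with a median correlation of 0.531 with the other ATAC libraries against 0.843 to 0.899 in the remaining controls. Without both libraries of that date 5857 peaks differed.

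In the DOX-labelled ATAC libraries (n = 3) the peak at chromosome 2, 10263167 to 10263967, rose from 2.90 ± 1.05 to 29.8 ± 6.61 CPM (log2 fold change 3.34 ± 0.28, adjusted p = 0.000167, edgeR with Benjamini-Hochberg adjustment). It fell in KO (−1.32, adjusted p = 0.0163). Peaks at chromosome 1, 21030319 to 21031469 (2.80), chromosome 11, 121416025 to 121416668 (2.79), chromosome 4, 108498215 to 108499111 (2.77), and chromosome 15, 93773332 to 93774306 (2.60), rose, the last of which also fell in KO (−0.98, adjusted p = 0.0407, edgeR). Lower peaks were at chromosome 14, 70735929 to 70736465 (−2.81), chromosome 12, 92019777 to 92020703 (−2.62), chromosome 1, 95938707 to 95939630 (−2.60), chromosome 11, 4290362 to 4291337 (−2.60), and chromosome 5, 75817581 to 75818423 (−2.59). These 5 calls were lost without DOX replicate 3 (adjusted p from 0.0551 to 0.164), the one on chromosome 5 also without DOX replicate 1 (0.0841) or 2 (0.0807) and that at 4290362 of chromosome 11 without DOX replicate 2 (0.0544). The peaks on chromosome 12, on chromosome 1 at 95938707 and on chromosome 5 were also lower in KO (−2.31, −2.36 and −2.57). Both comparisons share the controls, so a high control lowers both values. The chromosome 12 peak was at 29.7 CPM in control replicate 7 and at 5.85 to 11.9 in the other controls.

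In DOX 6086 of 88113 peaks differed, 4711 higher and 1375 lower (77.4% higher), and 1982 by 2-fold or more, of which 49% were higher. With total counts as the scaling 2444 differed (67.9% higher, and the median of all peaks was −0.208 in place of −0.156). With cyclic loess scaling 3064 differed (55.9% higher), and with the date block 8409 (59.5% higher). Without DOX replicate 1, 2 or 3, 3508, 3803 and 2103 peaks differed, of which 287, 268 and 164 were lower (91.8%, 93% and 92.2% higher). DOX and KO differed directly at 16392 peaks, 9635 higher and 6757 lower in DOX (58.8% higher). That count was 11330 with total counts (35.3% higher), 10740 with the date block, and 10483 and 9189 without DOX replicate 2 or 3. No ATAC date holds both DOX and KO libraries, so condition and date cannot be told apart in this comparison. Its date block rests on taking both control arms as equal, and those differed at 147 peaks.

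Of 817 peaks called in both comparisons, 81 were higher in both, 217 lower in both, 224 lower in KO and higher in DOX, and 295 higher in KO and lower in DOX, where independent lists would share 188.9, 53.35, 182.8 and 55.13. The excess among peaks lower in KO and higher in DOX turned with separate controls (63 against 69.01) and with the date block (219 against 376), and without DOX replicate 2 (69 against 92.31) or 3 (48 against 53.61) or control replicate 1 (156 against 168.1) or 6 (175 against 188). Peaks lower in both numbered 336 with separate controls (48.65 from independent lists) and 751 with the date block (256.2). Across peaks the fold changes correlated at r = 0.292 with a covariance of 0.187. In 8 simulated sets of unchanged groups against the same controls, without date pairing, these were 0.325 and 0.113. With separate controls r was 0.0998 and the covariance 0.0439, with the date block r was 0.0938, and without control replicate 2 it was −0.0618.

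**Figure D5:**
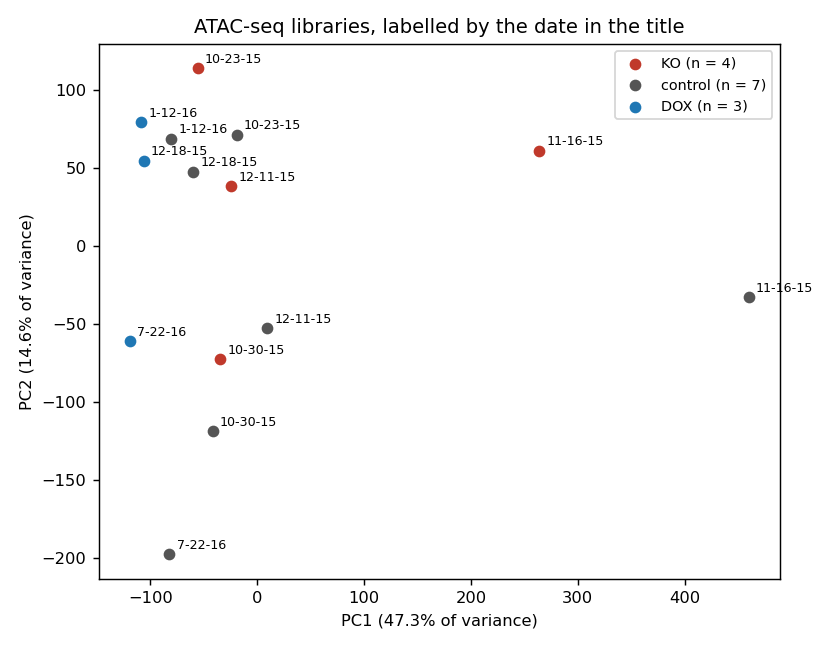
First and second principal components of the 14 ATAC libraries (47.3% and 14.6% of the variance), coloured by condition. The libraries of 16 November, control replicate 2 and KO replicate 4, lie at 460 and 263.8 on the first component, and the other 12 between −119 and 9.22.

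The controls of both title arms were compared as a background. Control RNA libraries titled as given no doxycycline (n = 4) differed from those titled wild type (n = 2) at 53 of 11673 genes, 14 higher and 39 lower, and control ATAC libraries (3 and 4) at 147 peaks, 137 higher and 10 lower. At an unadjusted p under 0.05 the counts were 1586 genes and 18007 peaks, and DESeq2 called 279 and 2148. With only these groups in the edgeR fit far more genes passed, as given in the closing part. On the first principal component of RNA the wild-type-titled controls lay at −5.51 and −3.89 and the no-doxycycline ones at −20.9 to −16.7. DOX lay at −46.4 to −39.6 there. On the second the no-doxycycline controls, at −38.6 to −29.5, lay further from DOX (29.9 to 36.9) than the wild-type-titled ones. The 53 calls thus do not show the arms to be alike. The RNA count fell to 17, 18, 10, 23 and 17 without control replicate 1, 2, 3, 4 or 5. Without control replicate 1 or 3 the wild-type-titled RNA arm is 1 library, which is assumed to vary like the other groups. The ATAC count ranged from 4 without control replicate 5 to 1329 without control replicate 2.

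The authors also gave a peak list per ATAC library, with 21940 peaks in control replicate 6 to 52850 in DOX replicate 2. Together the lists touched 91689 of the 96316 merged peaks, and 14924 were touched in all 14. The mean Jaccard overlap of the touched peaks was 0.566 between libraries of 1 condition and 0.534 between conditions, a difference of 0.0324 (one-sided exact permutation p = 0.0688 over 120120 labelings, which do not keep the dates). With condition swapped only within the 7 dates the exact p was 0.109 over 128 labelings. It was 0.0224 (exact p = 0.181) when a list had to cover 50 percent of the merged peak and 0.0197 (exact p = 0.313) for the 10000 peaks of highest score.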

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

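The tests of depth and of the RNA libraries in the second paragraph were chosen after the result was seen, and the test of added reads was set before. In groups of 4 to 10 libraries, 15 single values lay far from the rest of their group by Dixon's criterion, which by chance picks about 1 in 20 groups. Of 171 RNA groups tested 11 were picked where chance gives 8.55, of 40 ATAC groups 3 (chance 2) and of 12 groups of library measures 1 (chance 0.6). In KO replicate 1 Mamdc2 was at 26.4 CPM (others 10.1 to 13.5) and the Fc receptor gene Fcgr3 at 1.8 (2.9 to 3.06), and in KO replicate 5 Manf was at 135 (102 to 109). Control replicate 1 had Foxp3 at 3.5 CPM (0.15 to 0.651), Mamdc2 at 0.406 (at most 0.0751) and Ccr9 at 0.813 (at most 0.207). Control replicate 3 had Cmpk2 at 24.5 (11.7 to 15.9), Kit at 8.62 (19 to 24.3) and Eaf2 at 1.17 (0.476 to 0.6). Control replicate 2 held the only count of Klk1 among controls (0.0794 CPM), and Fkbp11 was at 0.849 in control replicate 5 (0.29 to 0.483). Among peaks, that at chromosome 4, 108498215 to 108499111, was at 1.92 CPM in KO replicate 1 (1.23 to 1.34). In control replicate 7 the peak at chromosome 5, 11256096 to 11256918, was at 59.5 (11.5 to 26.4) and that at chromosome 12, 92019777 to 92020703, at 29.7 (5.85 to 11.9).

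The last value was the median correlation of ATAC control replicate 2 with the other ATAC libraries, 0.531 against 0.843 to 0.899 in the other controls. In this library of 16 November, 11967 peaks were 4-fold or more higher than in the libraries of other dates and 434 as much lower, a ratio of 27.6, as added reads from another sample or cell type would give, and 11958 of them were also higher in KO replicate 4 of the same date. There the excess was a median of 29.4% of that in control replicate 2 (quartiles 26.3% and 32.9%), and those peaks held 21.4% and 10.2% of the counts of both libraries against at most 2.7% at other dates. Depth as the cause is argued against by its total of 7.16 M counts, inside the range of the other libraries. A broad change of the cells in RNA as well is argued against by the median correlations of the RNA libraries of that date. The lower was 0.95, inside the range of the other RNA libraries. A correlation over all genes does not cover single genes. RNA control replicate 1, named above for Foxp3, Mamdc2 and Ccr9, is of that date. Its Xist was 19.5 CPM before TMM scaling, against 2.41 to 3.6 in the other controls read as male. RNA KO replicate 2, also of that date, had the highest Foxp3 of the KO libraries (26 CPM). Reads from another sample or cell type, in 2 amounts, may therefore be a source of this pattern, though what they came from stays open. A state of the cells seen in ATAC alone, or in few genes of the RNA, was not tested.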

How the results depend on the processing

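Chosen after the data were seen were the sex covariate, the deposited log2 table, the 3 adjustment sets as a covariate, leaving out both libraries of 16 November, the date block for the ATAC relation and swaps within dates for the peak lists. Of the main results under their alternatives, 210 kept direction and side of the threshold or count within 1.5 times, 17 rose past it, 32 fell below it, 1 moved and 1 reversed. For named genes 1680 were kept, 28 lost and 1 gained a call and 11 reversed, all 11 without a call in either fit. For named peaks 442 were kept and 8 lost, and for gene lists 808, 58 lost, 32 gained and 1 reversed. Except where a limit of 2-fold or fewer libraries lowers a count by construction, the cause was not tested.

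Asking for 2-fold or more, RNA calls numbered 1023 (KO), 846 (DOX) and 1340 (DOX against KO), and ATAC calls 1982 (DOX) and 9734 (DOX against KO). With the date block as a pairing, 1593 genes were called in KO, of which 1536 were among the unblocked calls with the same sign, and 1927 in DOX against KO (1767 shared). Blocked ATAC calls numbered 11379 in KO (5753 shared) and 10740 in DOX against KO (7673 shared), where no date holds both conditions. The block changed no call of a main result or named gene, and no gene list, except those given in the report. Against the controls of the matching title arm 1406 genes were called in KO (1286 shared).

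For ATAC DOX against controls, 2444 peaks were called with total counts, 9474 with DESeq2, 3192 with only both groups in the fit, 3064 with cyclic loess and 10013 on the deposited log2 values. For ATAC no-doxycycline against wild-type controls, 260 were called with total counts, 2148 with DESeq2, 284 with cyclic loess, 276 on the log2 values, 863 without both libraries of 16 November and 863 with the adjustment sets as a covariate. With only those control groups in the edgeR fit 0 passed, and 7758 had an unadjusted p under 0.05. The RNA counterpart gave 98 genes without the filter, 279 with DESeq2, 24 with the sex covariate and 1217 with only those groups in the fit. Irf4 in DOX passed without the filter (−0.50, adjusted p = 0.0456) and with DESeq2 (−0.48, adjusted p = 0.0347), while its adjusted p reached 0.151 among the alternatives. Fry, which asks whether a list's genes move one way and does not compare them with other genes, lost 1 list call in KO and 3 in DOX, given in the report, and gained 6 in KO (adjusted p from 0.00266 to 0.0379) and 6 in DOX (0.000312 to 0.0283). With an estimated correlation 1 gene list was called in KO and 1 in DOX. The correlation of both RNA effects was 0.226 without the filter.

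Leaving out each library in turn gave 2306 to 2987 genes for RNA KO, 1931 to 2846 for RNA DOX, 3006 to 3657 for DOX against KO and 10 to 69 for the control arms. It gave 4248 to 8405 peaks for ATAC KO, 2103 to 7047 for ATAC DOX, 9189 to 13273 for DOX against KO and 4 to 1329 for the control arms. The Irf4 log2 fold change ran from −0.38 to −0.15 in KO and from −0.59 to −0.37 in DOX, gene lists called from 12 to 15 in KO and 8 to 13 in DOX, and the correlation of both effects from 0.109 to 0.171 in RNA and from −0.0618 to 0.516 in ATAC. The lowest ATAC correlation was the 1 reversal, without control replicate 2.

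The reversed signs were Rorc in DOX with the date block (−0.34), the matching arm (−0.18), the sex covariate (−0.065) and without DOX replicate 1 (−0.065; range without single libraries −0.065 to 0.62), and Foxp3 in DOX with the date block (0.73), the matching arm (1.04), and without DOX replicate 2 (0.05) or control replicate 1 (1.01; range −0.42 to 1.01). In KO they were Tcf7 (−0.035) and Gata3 (−0.081) against the matching arm and Batf with the sex covariate (−0.093). The G2/M list reversed in KO against the matching arm (adjusted p = 0.77).

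Not run for want of an mm9 genome and annotation were the motif window and the distance from peak to gene. The lowest ATAC depth was 4.79 M counts in DOX replicate 1. Simulated data had the depths, library numbers and fitted spread of these libraries but no date effects. There the ATAC test found 29% of 2-fold changes for KO and 23% for DOX, among peaks of a mean level above the median. The share of depth in this was not separated.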

Other observations

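The tests of the Irf4 level, of markers of other cells and of the calcium channel genes, the RNA regroupings against controls, and the ATAC regroupings by date, by pairs parted or for windows were chosen after the result was seen, while the other regroupings and the count of windows were set before. Genes called in both RNA comparisons, with at least 10 CPM and no overlap with the controls, were picked for this paragraph after their values were seen. Of these, 149 were higher in both KO-labelled and DOX-labelled libraries, among them the desmosome gene Dsp (log2 fold changes 3.94 and 3.51), the surface glycoprotein gene Cd24a (3.12 and 2.97) and the interferon-induced GTPase gene Gbp7 (2.28 and 2.38). In both, 171 were lower, such as Dock4 (−4.70 and −2.68), the transcription factor gene Cebpa (−7.41 and −2.38) and the vitamin D receptor gene Vdr (−2.72 and −1.89). Another 86 were lower in KO and higher in DOX, like Prdm1: Gpr25 (−5.02 and 3.05), the laminin gene Lamc1 (−3.26 and 3.03), Havcr2 (−3.57 and 2.98) and the costimulatory ligand gene Cd80 (−2.61 and 4.03). The remaining 56 were higher in KO and lower in DOX, among them Tnfrsf19 (3.40 and −2.66), Atp8b4 (3.66 and −2.09), Nrgn (2.77 and −1.69) and the inhibitory receptor gene Cd160 (1.45 and −1.49).

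Genes of voltage-gated calcium channels drew attention because Cacna1s (−4.87 in KO and 2.22 in DOX), Cacna1i (−3.62 and 3.36) and Cacnb3 (−1.54 and 2.41) were lower in KO and higher in DOX. Whether the family does so was tested on its other 6 measured genes, of which 0 were called lower in KO and higher in DOX, which argues against that joint pattern as a trait of the family. The rise in DOX alone was wider, with 7 of the 9 measured genes called higher and 4 of the other 6, among them Cacna1b (1.95), Cacna2d2 (1.72) and Cacnb1 (0.68), while 0 of those 6 were called lower in KO. Cacna2d4 was higher in both (adjusted p = 0.00499 and 0.00163, edgeR with Benjamini-Hochberg adjustment) and Cacna1d was higher in KO (1.13).

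Called ATAC peaks gathered in 1-Mb windows. Of 1956 windows with at least 10 tested peaks, 31 held more peaks higher in KO, 41 more lower in KO, 60 more higher in DOX and 9 more lower in DOX than expected at an adjusted p under 0.05, 141 in all, where 1000 random reassignments of the calls gave at most 2 for any of these. Reassigned calls treat neighbouring peaks as independent, so whole libraries were regrouped as well. The real grouping gave 72 windows in KO and 69 in DOX over both directions, other groupings at most 61 and 37, and 1 of 60 was as large in each. The other groupings had a median of 0 called peaks and 0 windows, so most could hardly reach such counts. Groupings that part as many same-date pairs gave 0 windows, but numbered 15 in KO and 7 in DOX, too few for a share under 0.05. The window counts thus do not exclude chance at the level of libraries. Regional signal particular to single libraries was not excluded. The most extreme stretch was at 11000001 to 12000000 of chromosome 5 (mm9), with 29 of 37 peaks lower in KO where 1.44 were expected (adjusted p = 5.94e-31). All 37 peaks were below 0 there, with a median log2 fold change of −2.55. The summed signal was 45.4 to 78.8 CPM in the 4 KO libraries, 174 to 1060 in the 7 controls and 233 to 336 in the 3 DOX libraries. Control replicate 7 was the highest control in this stretch, and the highest of all 14 libraries in 37 of its 37 peaks. Other windows were at 4000001 to 5000000 of chromosome 19, where 26 of 98 peaks were higher in DOX (5.24 expected), and at 63000001 to 64000000 of chromosome 4, where 17 of 69 were lower in DOX (1.08 expected).

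Irf4 mRNA was at 83.1% of the control level in the KO-labelled libraries and 71.3% in the DOX-labelled ones. Wrong labels of single libraries are argued against by all 15 RNA libraries having their nearest library in their own condition. Control cells making up most of the KO sort are argued against by 40 called genes, out of 2629 with at least 100 CPM in controls, that lay under 0.5 of the Irf4 ratio, with Il21 at 0.328% of control. A deletion that leaves most of the transcript counted may give the gene-level log2 fold change of −0.266 in KO, but it cannot be told apart from transcription of an intact gene, since the counts are summed over exons. For DOX, in which the water was changed before the sort, a return of the transcript to or below the control level is a further open, untested explanation.

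Itgam, Cd8a and Cd8b1, markers of other cell types, were higher in the DOX-labelled libraries, although the sort took CD4-positive donor cells and cells bearing CD8 or CD11b, the product of Itgam, were depleted before transfer. Myeloid cells in the sort are argued against by Lyz2, Tyrobp and Fcer1g, which myeloid cells express abundantly: the highest of them averaged 0.209 CPM in DOX, where Itgam averaged 150. CD8 T cells in the sort cannot be told apart from expression in the CD4 T cells, since Cd8b1 and Cd8a stood at a median ratio of 5.22 (4.55 to 5.54 in the 4 libraries, while the controls averaged 8.75 and 0.0746 CPM) and Cd4, at 1140 ± 234 CPM against 1050 ± 87.3, is too abundant to show a small share. Expression by the OT-II cells themselves stays open, since protein on single donor cells was not analysed here.

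Other groupings of the same libraries were used to ask whether chance could give as many calls. For RNA the real grouping, counted in each share, called the most genes in each comparison, a share under 0.05. KO against controls had 2893 genes (at most 69.7% as many in another grouping, 1 of 100 as large). DOX against controls had 2345 (at most 980, 1 of 100) and DOX against KO 3400 (at most 1767, 1 of 100). The other groupings had a median of 0 called genes in each, so most could hardly reach such counts. Groupings that part as many same-date pairs as the real one called at most 983 genes for KO (12 groupings), 980 for DOX (10) and 1767 for DOX against KO (54). The 12 and 10 are too few for a share under 0.05, so with dates kept chance is not excluded against controls. For gene lists chance is not excluded: 5 of 100 groupings gave at least 14 lists in KO and 31 of 100 at least 10 in DOX, with 15 the highest in both and medians of 8 and 7 of the 29 lists in the others. In ATAC DOX against KO only the real grouping reached its count (16392 peaks, 0 in every other grouping, 1 of 35 as large). The share is under 0.05, but groupings that call 0 peaks could hardly reach such a count. No ATAC date holds both of these conditions, so a difference between dates cannot be told apart from one between conditions there. For ATAC KO against controls 14 of 60 groupings called as many as 6952 peaks (at most 14145), and for ATAC DOX against controls 5 of 60 called as many as 6086 (at most 11216), so that chance is not excluded by the groupings as drawn. Those counts point to a structure of the samples, the libraries of 16 November. Among groupings with as many of these libraries in the first group as the real one, 0 of 25 reached the count in KO (at most 2379) and 0 of 43 in DOX (at most 653). Among those that part as many same-date pairs as the real one, 15 in KO called at most 0 and 7 in DOX at most 150, numbers too few for a share under 0.05, and with the date block the real groupings called 11379 and 8409. For the no-doxycycline against wild-type ATAC controls chance is not excluded (147 peaks, at most 451, 2 of 35 as large).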
